A study of Caenorhabditis elegans with 6 samples.

How the data were processed

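Total RNA was profiled from L1 larvae in 6 libraries, 3 wild type and 3 *mrg-1* mutant, which the series' design text calls biological replicas. Per the labels' protocols, the mutant larvae came from 2000 to 4000 hand-picked homozygous adults that did not carry the balancer, and the wild-type larvae from a similar number of adults washed off plates, so that picking and washing cannot be separated from genotype. RNA was isolated with a PicoPure kit and DNase, and libraries were made from 2 ng with the NuGEN Ovation v2 total RNA kit and an Illumina TruSeq kit, per the labels.

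The authors deposited a table of raw counts for 20392 genes with a length for each gene, and a table of normalized log2 values. Checked against the counts, each deposited log2 value is log2 of the count times 1 factor per library plus 8, where the factor brings every library to 24838462 counts. The genome build is ce10 per the submitters' processing notes. The aligner, counter, annotation, strand setting and treatment of reads that match several genes are not given in the sources used here. Overlapping and antisense genes are therefore uncertain as well as members of similar families. No sample column was left without a sample (0 unmapped).

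Of the gene identifiers, 19870 were in the Ensembl annotation of WBcel235 and 522, with 0.45% to 0.79% of each library's counts, were not; these were kept under their identifiers. Positions are those of WBcel235, another build than ce10, looked up by identifier, and were not converted. Symbols came from RefSeq's WBcel235 table by sequence name for 19844 genes. The deposited length of the mitochondrial gene *ND3* was 2855, against 336 bases annotated from 11356 to 11691, and the large ribosomal RNA lies next to it at 10403 to 11354. *ND3* alone held 47.4% to 72.1% of the mitochondrial counts of each library.

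Library totals were 19238422 to 39063186 counts. A group floor of 3 counts equals 0.0397 CPM in the wild type and 0.0392 CPM in the mutant. Where a group had 0 counts, the fold is a lower bound against that floor; with 1 to 3 counts, the ratio of summed counts is given with an exact 95% binomial interval. Floors and intervals cover counting error only. No pair of libraries agreed within sampling noise: the chi-square statistic per gene was 75 or more in each pair.

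Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, default expression filter, 13460 genes kept, quasi-likelihood F test, group as the only term, Benjamini-Hochberg 0.05). Standard errors are those implied by the F statistic, the absolute log2 fold change divided by its square root. CPM are TMM-scaled. With 3 libraries per group the common dispersion was 0.339, and the median SD of log2 CPM was 0.72 in the wild type and 0.42 in the mutant. Tested on simulated data for this comparison (10 simulations, 13006 to 13064 genes run), the fit recovered on average 4.01% of genes changed 2-fold (0% to 12%), 45.5% of those changed 4-fold (40.8% to 50%), 72.3% at 8-fold (66% to 83.7%) and 87.3% at 16-fold (80% to 92%). It made 58 false calls among 1097 in all, and 0 calls in 1 simulation where no gene changed. Changes were planted only in genes with a mean above 1 CPM. Both groups were drawn with the same dispersion per gene, unlike the data, where the wild type spread more. The rates therefore need not hold for weaker genes or for this unequal spread. Absence of a call says little about changes under 4-fold.

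Gene sets were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with fry and an estimated correlation beside it. The sets were 27 lists written from textbook knowledge, 23 families defined by symbol, of which 21 had at least 3 tested members, and 7 chromosome sets. With an estimated correlation 0 list and 0 family calls and 4 chromosome calls held in limma's camera, where 3 lists, 5 families and 4 chromosome sets had an unadjusted p under 0.05. No gene list was taken from the study. The lists, the tests and the rule for named genes were fixed before the data were examined. Named are *mrg-1*; the 10 largest rises and 10 largest falls among called genes with at least 5 CPM in the higher group and no overlap of the groups; for each list or family with a called member, up to 4 with the smallest adjusted p; and any gene a count of 5 or fewer refers to. Alternatives were other scalings and filters, DESeq2 1.42.0, limma on voom weights and on the authors' deposited log2 values, a replicate block, stricter thresholds and each library left out. A further 4 were added after seeing the data (mitochondrial genes left out, libraries thinned to 17191073 nuclear counts, library quality weights, wild-type library 1 alone). Figures were drawn with matplotlib 3.10.9.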

Results

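Total RNA was sequenced from first-stage (L1) larvae of *Caenorhabditis elegans*, 3 libraries from the wild-type strain N2 and 3 from larvae whose mothers were homozygous for a mutation in *mrg-1*, the gene of a chromodomain protein that binds chromatin. Embryos hatched in buffer for 18 h and were fed for 2 h and 30 min. The wild-type libraries held 19238422, 28964051 and 39063186 counts and the mutant libraries 24123189, 20917771 and 23575372. Mitochondrially encoded genes took 10.64%, 23.12% and 45.56% of the counts in wild-type libraries 1, 2 and 3, and 8.42% to 12.43% in the mutant libraries. Without these genes the totals were 17191073, 22267493 and 21267888 in the wild type and 21124151, 19156842 and 20871534 in the mutant. Counts thinned to one nuclear depth covered 14767 ± 750 genes in the wild type and 16490 ± 489 in the mutant (mean ± SD, n = 3 each). The wild-type libraries were also less alike: across genes, log2 CPM correlated at 0.860 to 0.888 among them and at 0.928 to 0.940 among the mutant libraries. Libraries 2 and 3 were the least alike wild-type pair (0.860, against 0.863 for 1 and 3 and 0.888 for 1 and 2). Set medians given below against libraries 2 and 3 were taken against the mean of these unlike libraries. Wild-type library 1 correlated with the mutant libraries at 0.884 to 0.911, above the wild-type libraries 2 and 3, at 0.816 to 0.852.

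The *mrg-1* transcript (WBGene00003406) was lower in each mutant library than in any wild-type library. The gene lies on the minus strand of chromosome III, 12871029 to 12874656 in WBcel235. Its level was 30.2, 15.9 and 18.8 CPM in the wild-type libraries and 2.11, 5.61 and 5.15 CPM in the mutant ones, a mean of 21.6 ± 7.57 against 4.29 ± 1.90 CPM (SD, n = 3 each). The transcript was 5.04-fold lower in the mutant, with a log2 fold change of -2.33 (SE 0.53, adjusted p = 0.0413, edgeR quasi-likelihood test). The labels do not say which part of the gene is lost, and the position of the remaining counts, 54 to 137 per library, cannot be read from a table by gene. The call passed narrowly. In edgeR it was lost without wild-type library 1 (adjusted p = 0.06) or 2 (0.0735) and without mutant library 1 (0.181), 2 (0.138) or 3 (0.16), while the log2 fold change stayed between -2.54 and -1.99. Over the alternatives tried the adjusted p ran from 0.000267 (DESeq2) to 0.205 (edgeR against a 2-fold minimum).

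The comparison of mutant with wild-type larvae asked which genes depend on *mrg-1* at this stage. Genes of the antimicrobial response, C-type lectins, F-box proteins and cuticle collagens stood among those that rose in the mutant. Among those that fell were the replication gene *mcm-7*, the kinetochore gene *knl-1*, the proteasome subunits *pas-3* and *rpn-9* and the retinoblastoma-related repressor *lin-35*. The infection response gene *irg-5* rose from 2.02 ± 1.07 to 79.9 ± 31.9 CPM (39.6-fold). The C-type lectin *clec-17* rose from 22.1 ± 5.19 to 236 ± 60.7 CPM (10.7-fold; SD, n = 3 each). The lysozyme gene *lys-4* fell from 35.3 ± 9.32 to 3.20 ± 2.47 CPM, 11-fold lower. Of 13460 genes tested, 350 changed, 236 higher and 114 lower, each by at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg 0.05). In all 350 the 3 libraries of one group lay beyond the 3 of the other, which held for 26.4% of the tested genes against 10% by chance.

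The count and its split depended on the libraries and the scaling. Without mutant library 1, 2 or 3 the edgeR count fell to 35, 67 or 44 genes, without wild-type library 2 it was 82, and without wild-type library 1 it was 1043. DESeq2 called 1534. Of 72 named genes, 14, 24 or 18 were called without mutant library 1, 2 or 3, 26 or 54 without wild-type library 2 or 3, and 68 without wild-type library 1. The fitted fold of 31 of them moved by over 1.5 times when some library was left out. Scaled to library totals alone, 204 genes were higher and 11 lower, and in the authors' normalized table limma called 480 higher and 34 lower. These scalings moved the median log2 fold change of the tested genes from -0.03 to 0.272 and 0.348.

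The 10 largest rises among called genes of at least 5 CPM were in genes nearly silent in the wild type. *mfsd-8.4*, of the major facilitator transporter family, rose from 0.0282 ± 0.0251 to 23.7 ± 14.1 CPM (2 against 1844 counts, ratio 909, 95% counting interval 251 to 7520). The C-type lectin *clec-74* had 3 against 1448 counts (ratio 476, 163 to 2310), *F55G11.7* 1 against 548 (ratio 541, 96.6 to 21400) and *aaim-1* 1 against 445 (ratio 439, 78.4 to 17400). *nas-38*, of the astacin metalloprotease family, had 2 against 743 (ratio 366, 101 to 3030), and the caenacin peptide gene *cnc-6* had 2 against 528 (ratio 260, 71.7 to 2160). *Y58A7A.3* rose 290-fold to 50.7 ± 17.9 CPM, *clec-174* 253-fold to 15.5 ± 5.45, *C38D9.2* 102-fold to 29.9 ± 11.3 and *ZK6.8* 90.4-fold to 8.83 ± 4.53 CPM (SD, n = 3). The edgeR adjusted p values of these genes lay between 0.000273 and 0.0182. Mutant libraries differed in some of them: *nas-38* stood at 4.76, 1.11 and 22.3 CPM. Without mutant library 3 the log2 fold changes of *nas-38* and *cnc-6* went from 8.25 to 6.60 and from 7.72 to 6.58. That of *nas-38* was 10.88 without wild-type library 3, and that of *F55G11.7* went from 8.63 to 10.48. For *aaim-1* it went from 8.26 to 10.24 without wild-type library 1. All 4 wild-type counts of *clec-174* were in library 1, and its log2 fold change went from 7.98 to 11.67 without that library. Without wild-type library 3 it went from 8.18 to 9.18 for *Y58A7A.3* and from 6.50 to 7.53 for *ZK6.8*. A further 23 genes that rose had no count in any wild-type library.

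The 10 largest falls, by the same rule, included *fat-7*, a stearoyl-CoA desaturase of fatty acid synthesis, from 8.22 ± 4.89 to 0.151 ± 0.262 CPM (53.5-fold lower), and *cpg-2*, an eggshell chondroitin proteoglycan, from 8.30 ± 5.25 to 0.215 ± 0.226 CPM (37.4-fold lower). The cell cycle phosphatase *cdc-25.1* fell from 20.2 ± 3.72 to 2.26 ± 1.66 CPM (8.88-fold lower), and the glucuronosyltransferase *ugt-57* from 31 ± 13.3 to 3.71 ± 1.26 CPM (8.35-fold lower; SD, n = 3 each). The other falls were *slc-25A32* (11.9-fold), *lys-4* (11-fold), *glrx-22* (9.95-fold), *pud-4* (9.40-fold), *fipr-1* (8.81-fold) and *E02H4.7* (7.57-fold). Their edgeR adjusted p values ran from 0.0139 to 0.046. *E02H4.7*, *fipr-1* and *glrx-22* were lowest among wild-type libraries in library 1, at 7.64, 12.1 and 8.36 CPM. In wild-type libraries 2 and 3 they stood at 24.1 and 51.3, at 44.7 and 82.1 and at 34.7 and 38.6 CPM. *slc-25A32*, *pud-4* and *lys-4* were also lowest in library 1, at 15.1, 9.56 and 29.7 CPM, against 28.2, 14.9 and 30.2 CPM in library 2. All 11 mutant counts of *fat-7* were in mutant library 2, and its log2 fold change went from -5.74 to -10.7 without that library. Without mutant library 3 that of *cpg-2* went from -5.23 to -6.31, and without mutant library 2 those of *lys-4* and *pud-4* from -3.46 to -4.18 and from -3.23 to -4.14. Without wild-type library 3 those of *cpg-2*, *slc-25A32*, *pud-4*, *fipr-1* and *E02H4.7* were -4.59, -2.98, -2.63, -2.42 and -2.1.

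**Figure D1:**
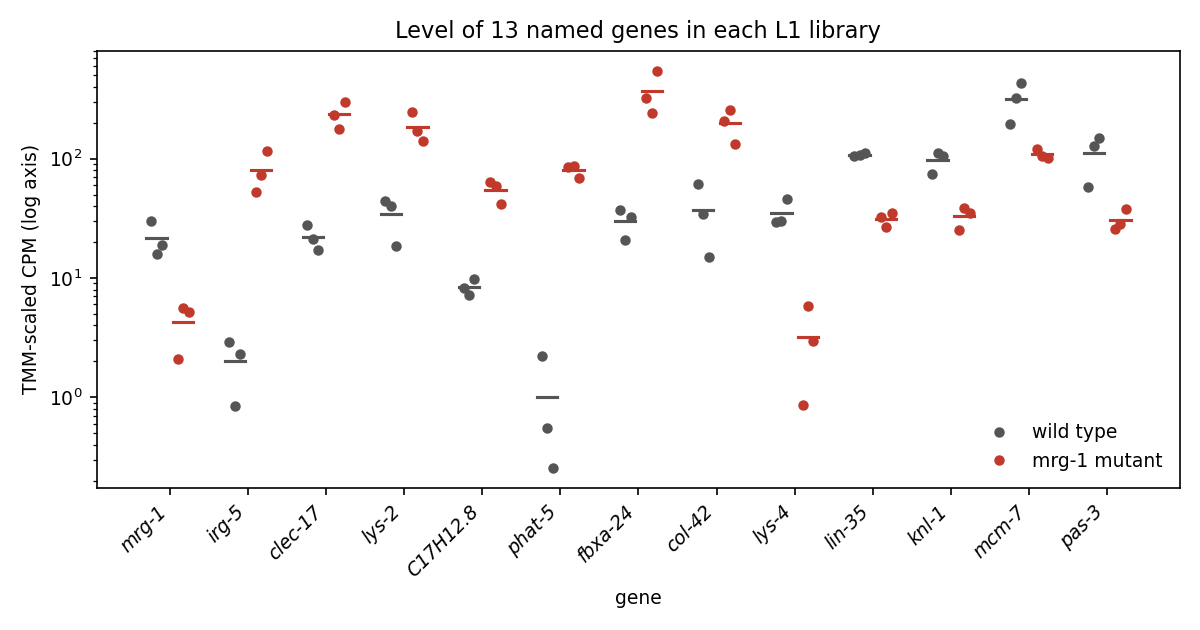
TMM-scaled CPM (log axis) of 13 named genes in each library; points are single libraries, grey for wild type and red for the *mrg-1* mutant, and bars are group means (n = 3). *irg-5* stood at 2.02 CPM in the wild type and 79.9 in the mutant, and *lin-35* at 108 and 31.5 CPM, with no overlap between the groups in any gene drawn.

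Innate immune effectors gave the most calls of any gene list. Of 27 tested effectors of the antimicrobial response, 7 rose (16 when adjusted over the list alone) and 1, *lys-4*, fell (3 adjusted over the list alone), with a median log2 fold change of 1.46. After *irg-5*, the lysozyme gene *lys-2* rose from 34.5 ± 14 to 186 ± 55.3 CPM (log2 fold change 2.43, SE 0.38), *C17H12.8* from 8.45 ± 1.30 to 54.7 ± 11.6 CPM (2.69, SE 0.37) and *hpo-6* from 6.41 ± 4.87 to 56.4 ± 13.2 CPM (3.14, SE 0.55; SD, n = 3 each). Their edgeR adjusted p values were between 0.00528 and 0.0164. Without wild-type library 1 the log2 fold change of *hpo-6* was 3.91. The list ranked above other genes in limma's camera test (adjusted p = 5.5e-05), but not with an estimated correlation (limma camera adjusted p = 0.42). The median stood 2.02 above wild-type library 1 and 1.79 above wild-type libraries 2 and 3 on the log2 scale. The list of the intracellular pathogen response, which *pals* genes mark, had a median of 0.61 over 14 genes, with 0 called in edgeR and 0 adjusted over the list alone (3 higher at an unadjusted p under 0.05, 2 in DESeq2 and 0 in limma-voom). Its limma camera adjusted p was 0.032, and 0.42 with an estimated correlation, 0.1 without mutant library 2 and 0.0046 to 0.42 over the alternatives. Its median was 0.97 against wild-type library 1 and 0.86 against libraries 2 and 3.

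Genes of DNA replication and the cell cycle had a median log2 fold change of -0.72, lower than other genes in limma's camera test (adjusted p = 3.5e-05), but not with an estimated correlation (adjusted p = 0.42). Of 33 tested, 2 fell, the replicative helicase subunit *mcm-7*, from 317 ± 120 to 109 ± 10.5 CPM (2.91-fold lower), and the kinetochore gene *knl-1*, from 97.1 ± 19.3 to 33 ± 7 CPM (2.94-fold lower; SD, n = 3 each). Their edgeR adjusted p values were 0.0299 and 0.031, and 6 fell when adjusted over the list alone. The list's median was -0.69 against wild-type library 1 and -0.72 against libraries 2 and 3. In the synMuv B and DREAM list 1 of 19 genes fell, also 1 adjusted over the list alone. This was the retinoblastoma-related *lin-35*, from 108 ± 3.59 to 31.5 ± 4.28 CPM (log2 fold change -1.78, SE 0.29, edgeR adjusted p = 0.0139). The list as written also named the synMuv A genes *lin-8*, *lin-15A*, *lin-38* and *lin-56*. It shares *lin-13*, *hpl-2*, *lin-61* and *met-2* with the heterochromatin list given below. Its median was -0.46 (limma camera adjusted p = 0.0041, and 0.42 with an estimated correlation), -0.64 against wild-type library 1 and -0.39 against libraries 2 and 3. The P granule and small-RNA list had a median of -0.60 over 25 genes, with 1 fallen in edgeR, the RNA helicase *cgh-1*, from 640 ± 129 to 287 ± 46.3 CPM, and 4 adjusted over the list alone. Its limma camera adjusted p was 0.033, and 0.61 with an estimated correlation. The list of H3K9 methylation, heterochromatin and the nuclear lamina had a median of -0.48 over 26 genes with 0 called in edgeR and 0 adjusted over the list alone. It had 5 lower at an unadjusted edgeR p under 0.05, 2 in DESeq2 and 0 in limma-voom. As written it also named *mes-2*, *mes-3*, *mes-6*, *spat-3*, *npp-1* and *npp-3*, so it does not stand for H3K9 methylation alone. Its limma camera adjusted p was 0.033, and 0.42 with an estimated correlation. Without wild-type library 1 these last 2 lists were no longer called in limma's camera test (adjusted p = 0.3 and 0.16), nor without mutant library 1 (0.22 and 0.076). Their medians were -0.99 and -0.49 against wild-type library 1, and -0.28 and -0.18 against libraries 2 and 3. The P granule list was also lost without wild-type library 3, with a CPM filter and with thinned libraries (limma camera adjusted p = 0.089, 0.056 and 0.054, range over the alternatives 0.00095 to 0.61). The heterochromatin list was lost without mutant library 2, under library totals, in the authors' normalized table, with a CPM filter and with the replicate block (limma camera adjusted p = 0.05, 0.056, 0.052, 0.056 and 0.051, range 0.002 to 0.42).

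Muscle and pharynx lists lay above wild type on average, but level with wild-type library 1. For body wall muscle the median log2 fold change was 0.40 over 33 genes, with 0 called in edgeR and 0 adjusted over the list alone (9 higher at an unadjusted p under 0.05, 3 in DESeq2 and 2 in limma-voom). For the pharynx it was 0.43 over 22 genes, of which 2 rose, also 2 adjusted over the list alone. These were *phat-5*, from 1.01 ± 1.05 to 80.2 ± 9.69 CPM (81.5-fold), and *phat-4*, from 1.12 ± 0.757 to 13.4 ± 1.58 CPM (12-fold; SD, n = 3 each), both of which encode pharyngeal gland toxin-related peptides, with adjusted p values of 0.00112 and 0.0295 in edgeR. Without wild-type library 1 the log2 fold change of *phat-5* went from 6.35 to 7.62. The limma camera adjusted p values of the lists were 0.024 and 0.049, both 0.66 with an estimated correlation. Mutant libraries stood 0.06 and 0.02 above wild-type library 1 and 0.65 and 0.70 above wild-type libraries 2 and 3 in the medians of these lists. Against library 1 alone the limma camera adjusted p values were 0.95 and 0.53. The muscle call was also lost without wild-type library 2 or 3 (0.09 and 0.21) or mutant library 1 or 2 (0.095 and 0.097). The pharynx call was lost without any of these (0.098, 0.21, 0.095 and 0.1) or mutant library 3 (0.074), under library totals (0.056), without a filter (0.11), with the replicate block (0.062) and without mitochondrial genes (0.051). In limma's camera and fry the adjusted p values ran from 0.0046 to 0.95 and from 0.023 to 0.66 over the alternatives. Sperm genes had a median of 2.21 over 8 genes of low level, with 0 called in edgeR, 3 higher at an unadjusted p under 0.05, 2 in DESeq2, 0 in limma-voom and 1 adjusted over the list alone. The limma camera adjusted p was 0.013, and 0.42 with an estimated correlation, 0.39 against wild-type library 1 alone, 0.062 and 0.15 without wild-type library 2 or 3 and 0.14 without mutant library 2 (range 0.0044 to 0.42). Their median was 1.43 against wild-type library 1 and 2.78 against libraries 2 and 3. The 12 mitochondrially encoded genes had a median of -1.46, with 0 called in edgeR and 8 lower adjusted over the list alone (8 lower at an unadjusted p under 0.05, 6 in DESeq2 and 0 in limma-voom). Their limma camera adjusted p was 0.016, and 0.66 with an estimated correlation, 0.12 without wild-type library 3 and 0.053 and 0.063 without mutant library 2 or 3 (range 0.00096 to 0.66). Their median was 0.06 against wild-type library 1 and -1.49 against libraries 2 and 3. These 2 libraries carried 23.12% and 45.56% of their counts in these genes. *ND3* alone held 5.04%, 16.66% and 31.02% of the counts of wild-type libraries 1, 2 and 3, while *COX1* held 1.84%, 1.52% and 4.06%. The excess of library 2 was thus not shared by all these genes. The deposited length equalled the annotated one in only 5 of the 12, so what the other entries count is uncertain.

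The other 17 lists were not called by limma's camera over the 6 libraries. The vitellogenin list was called in limma's camera without wild-type library 3 (adjusted p = 0.019) or mutant library 1 or 2 (0.027 and 0.032; range over the alternatives 0.019 to 0.66). Against wild-type library 1 alone, camera in limma called germ cell identity, meiosis and MRG-1-related lists lower (adjusted p = 0.014, 0.036 and 0.007; highest over the alternatives 0.87, 0.94 and 0.94). Their medians were -0.49, -0.49 and -0.43 against that library and -0.19, 0.07 and 0.13 against libraries 2 and 3. The MRG-1-related list of 29 genes holds *mrg-1* itself, the mutated gene, whose fall tells nothing of the other factors. Its 2 members called over the 6 libraries were *mrg-1* and *hda-1*, both lower. Median log2 fold changes were 0.33 for pan-neuronal genes, 0.30 for neurotransmitter and neuron type genes, 0.23 for ciliated neurons, 0.29 for intestine, 0.29 for starvation genes and 0.31 for molting genes. They were 2.03 for the 3 vitellogenin genes, 0.12 for 5 cuticle collagens with a mutant phenotype, 0.13 for excretory cell, glia and coelomocytes and 0.10 for oocyte and eggshell genes. They were -0.40 for germ cell identity, -0.24 for meiosis, -0.52 for heat shock and unfolded protein response, -0.18 for heterochronic genes, -0.20 for early embryonic genes, -0.09 for dosage compensation and 0 for the chromatin factors related to MRG-1. Meiosis, heterochronic, early embryonic and dosage compensation lists changed the sign of their median under library totals or the authors' normalized table, and the MRG-1-related median lay between -0.01 and 0.32 over the scalings. The mean went against the median for oocyte genes (-0.37), dosage compensation (0.02) and early embryonic genes (0.52). It was -0.16 for MRG-1-related factors, *mrg-1* included. For the cuticle collagens the mean was 1.98, the median lay between 0.12 and 1.23 over the scalings, the highest without mitochondrial genes, and limma's fry gave an adjusted p of 0.025. The limma test ranked the molting genes and the excretory cell, glia and coelomocyte genes lower although their medians were positive. Single genes fell in some of these lists, the histone deacetylase *hda-1* (2.61-fold lower, 130 ± 15.2 CPM in the mutant), the mitochondrial chaperone *hsp-60* (2.31-fold lower, 287 ± 47.4), the acid phosphatase *pho-1* (2.69-fold lower, 176 ± 38) and *let-653* (4.65-fold lower, 14.8 ± 9.46 CPM). The insulin receptor gene *daf-2* rose 2.22-fold to 492 ± 103 CPM, *peb-1* 4.36-fold to 25.4 ± 3.48 CPM, and the cuticle collagen *rol-6* at least 57.4-fold from 0 counts (52.4-fold without mutant library 1) to 2.28 ± 0.622 CPM (SD, n = 3 each). Their edgeR adjusted p values ran from 0.0201 to 0.0467.

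C-type lectins gave the most calls of any gene family. Of 103 tested, 18 rose (22 adjusted over the list alone) and 0 fell (4 adjusted over the list alone, 8 at an unadjusted p under 0.05, 8 in DESeq2 and 0 in limma-voom), led by *clec-74*, *clec-17*, *clec-66* (14.3-fold, from 4.25 ± 0.794 to 60.8 ± 20.9 CPM) and *clec-174*. Their edgeR adjusted p values were 0.000273 to 0.00528. The family median was 0.57 (limma camera adjusted p = 0.0012, and 0.35 with an estimated correlation). It was 0.34 against wild-type library 1 and 0.83 against libraries 2 and 3 in log2 CPM. The *pals* genes, of which 24 were tested, had a median of 1.58 with 3 risen and 11 adjusted over the list alone (limma camera adjusted p = 7.7e-08, and 0.15 with an estimated correlation). These were *pals-26* (47.8-fold, to 6.72 ± 1.64 CPM), *pals-12* (1 against 307 counts, ratio 303, 95% counting interval 53.9 to 12000) and *pals-33* (at least 59.1-fold, to 2.35 ± 1.78 CPM; 38.1-fold without mutant library 3), with edgeR adjusted p values of 0.0164 to 0.0381. The *pals* median stood 2.18 above wild-type library 1 and 1.57 above libraries 2 and 3.

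Some collagens, F-box genes and cytochromes P450 rose as well, 6 of 55, 6 of 137 and 5 of 60 tested. These families ranked higher in limma's camera test, and none of them did with an estimated correlation (adjusted p = 0.35, 0.35 and 0.26). The collagen median was 1.02 over 55 genes, with 6 risen, among them *col-107* (7.28-fold), *col-42* (5.36-fold) and *col-98* (7.23-fold, to 108 ± 62.4 CPM). Adjusted over the list alone, 8 were higher and 1 lower (limma camera adjusted p = 0.00016; 0.1 against wild-type library 1 alone, range over the alternatives 2.3e-05 to 0.35). F-box genes had a median of 0.49 over 137 with 6 risen, led by *fbxa-24* (from 30.2 ± 8.30 to 371 ± 159 CPM), *fbxa-136* (11.4-fold) and *fbxa-69* (7.53-fold), while *fbxa-170* had no wild-type count and rose at least 50.8-fold (38.9-fold without mutant library 3). In this family 12 were higher and 1 lower adjusted over the list alone (limma camera adjusted p = 3e-04). Of 60 cytochrome P450 genes 5 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.93 (limma camera adjusted p = 0.00043). The 5 were *cyp-34A6* (32.7-fold), *cyp-33C8* (7.81-fold, to 67.2 ± 14.1 CPM), *cyp-34A10* (log2 fold change 5.94), *cyp-33C1* (1 against 197 counts, ratio 194, 34.5 to 7710) and *cyp-33D3* (at least 37.1-fold), and the fall was *cyp-13A2* (3.23-fold lower). The log2 fold changes of *cyp-34A6*, *cyp-33C8* and *cyp-34A10* ranged from 4.63 to 5.65, 2.53 to 3.60 and 5.26 to 7.38 over the left-out libraries, and that of *cyp-33C1* from 6.56 to 9.07. *cyp-33D3* stood at 0.429, 1.03 and 2.97 CPM in the mutant libraries, its bound was 18.4-fold without library 3, and edgeR called it in 0 of the 6 fits with a library left out. Against wild-type library 1 and against libraries 2 and 3 the medians were 0.47 and 1.31 for collagens, 0.98 and 0.88 for F-box genes and 0.43 and 1.29 for cytochromes P450. Nuclear hormone receptors had a median of 0.45 over 206 genes with *nhr-112* risen 13.7-fold, also 1 adjusted over the list alone (limma camera adjusted p = 0.0012, and 0.15 with an estimated correlation). The ABU and PQN genes had a median of 0.57 over 44, with *abu-14* and *pqn-71* risen, at 13.4 ± 18.6 and 18 ± 23.7 CPM in the mutant. Without mutant library 3 their log2 fold changes went from 5.81 to 3.50 and from 5.29 to 3.24, and *pqn-71* was called in 0 of the 6 left-out fits. Adjusted over the list alone 5 were higher (limma camera adjusted p = 0.0012, and 0.20 with an estimated correlation). Chemoreceptors had a median of 0.35 over 242 genes (limma camera adjusted p = 3e-04, and 0.20 with an estimated correlation), below the median of 0.51 of genes matched on expression. The 5 that rose, 7 higher and 1 lower adjusted over the list alone, were *srw-85* (60.6-fold, to 196 ± 22.2 CPM), *srr-6* (17.8-fold), *str-112* (log2 fold change 3.28), *str-204* (at least 117-fold) and the pseudogene *srz-76* (at least 44.8-fold). *str-204* stood at 11.2, 2.06 and 0.714 CPM in the mutant libraries, and its bound was 34.9-fold without library 1, while that of *srz-76* was 31.4-fold without mutant library 3. The call of *str-204* held in 2 of the 6 fits with a library left out. Without wild-type library 3 the log2 fold changes of *srw-85*, *str-112* and *nhr-112* went to 6.70, 4.21 and 4.49, from 5.92, 3.28 and 3.78. In the fungus-induced and caenacin peptide family, with a median of 0.42 over 17 genes, *cnc-6* rose and *fipr-1* fell, against 2 and 1 adjusted over the list alone. The family was called by camera (limma adjusted p = 0.032, and 0.35 with an estimated correlation; 0.31 without wild-type library 1 and 0.077 without mutant library 2, range 1.6e-05 to 0.35). Against wild-type library 1 and against libraries 2 and 3 the medians were 0.28 and 0.69 for nuclear hormone receptors, 0.49 and 0.58 for ABU and PQN genes, 0.52 and 0.76 for chemoreceptors and 1.14 and 0.20 for the fungus-induced family.

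Proteasome subunits had a median log2 fold change of -0.53 and ranked lower in limma's camera test (adjusted p = 2.2e-05), but not with an estimated correlation (adjusted p = 0.15). Of 32 tested, 2 fell (4 adjusted over the list alone): the core subunit *pas-3*, to 30.5 ± 6.33 CPM (3.67-fold lower), and the lid subunit *rpn-9*, from 170 ± 62.5 to 66 ± 7.54 CPM (2.58-fold lower; SD, n = 3 each). Their edgeR adjusted p values were 0.0294 and 0.0461. The family's median was -0.63 against wild-type library 1 and -0.51 against libraries 2 and 3. Ribosomal protein genes had a median of -0.24 over 75 with 0 called in edgeR and 0 adjusted over the list alone, 4 lower at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom. The limma camera adjusted p was 0.0012, and 0.78 with an estimated correlation. Under the scalings tried this median lay between -0.26 and 0.04, and the camera call was lost without wild-type library 2 (0.061) or mutant library 3 (0.16) and against wild-type library 1 alone (0.085; range 5.7e-07 to 0.78). The median was -0.13 against that library and -0.35 against libraries 2 and 3. The remaining 10 families were not called by limma's camera over the 6 libraries. Their medians were -0.31 for histones, 0.57 for hedgehog-related genes (with *grl-24* risen 17.5-fold), 0.24 for neuropeptide-like proteins, 0.26 for MATH and BATH genes, 0.13 for FMRFamide-like peptides, and -0.04 for transthyretin-related genes (with *ttr-50* risen 47.4-fold). They were 0.06 for UDP-glucuronosyltransferases (with *ugt-29* risen 11-fold and *ugt-57* fallen), -0.10 for homeobox genes, -0.06 for glutathione S-transferases (with *gst-24* and *gsto-3* risen 3.90-fold and 8.08-fold and *gsto-1* 6.05-fold lower) and -0.35 for insulin-like peptides. Some of these were called in alternatives. Histones were called lower without wild-type library 3 (limma camera adjusted p = 0.039), without mutant library 1 (0.042) and without a filter (0.035). Neuropeptide-like proteins were called higher without wild-type library 2 (0.018) or 3 (0.011), and the hedgehog-related genes higher without wild-type library 1 or 3 (0.026 and 0.0062) or mutant library 1 or 2 (0.0056 and 0.0087), without a filter (0.014) and with the replicate block (0.035). Against wild-type library 1 alone, neuropeptide-like, FMRFamide-like, transthyretin-related and insulin-like genes were called higher in limma's camera test (adjusted p = 6.8e-08, 0.00027, 1.7e-06 and 0.0062). Over the alternatives the limma adjusted p values of the histone, neuropeptide-like and hedgehog-related families ran from 0.035 to 0.39, 6.8e-08 to 0.9 and 0.0056 to 0.5. Without wild-type library 1 the log2 fold change of *ttr-50* went from 5.57 to 8.44 and that of *gsto-3* from 3.02 to 3.96. The transthyretin, homeobox, glutathione S-transferase and insulin medians changed sign under library totals or the authors' normalized table. The means of the homeobox (0.25), glutathione S-transferase (0.12) and insulin (0.06) families went against their medians. Members of these families resemble each other in sequence, and how the counting treated shared reads is not given in the sources used here, so single members are uncertain.

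**Figure D2:**
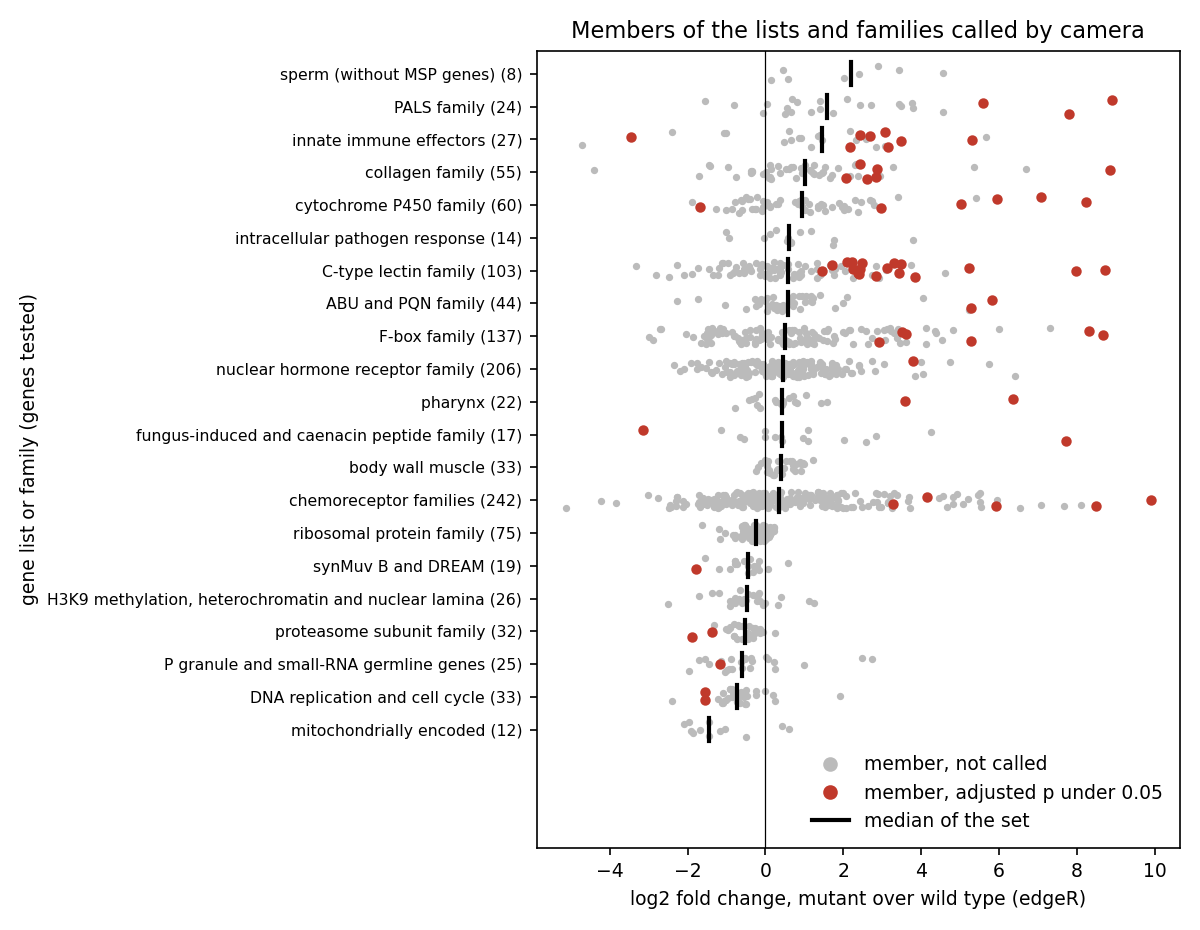
Log2 fold change (x axis, mutant over wild type, edgeR) of the members of the 21 gene lists and families called by limma's camera with a preset correlation (y axis, number of genes tested in brackets). Grey points are members not called, red points members with an edgeR adjusted p under 0.05, and black bars medians, which run from 2.21 for sperm genes to -1.46 for mitochondrially encoded genes; the ribosomal protein median, at -0.24, changes sign under other scalings.

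Genes on chromosome X were higher in the mutant than autosomal genes, by a small amount that recurred in each library. The median log2 fold change was 0.25 over 2017 X-linked genes and -0.10 over 11141 autosomal genes, and 62.8% of the X-linked genes against 45.7% of the autosomal ones had a positive value. Relative to the wild-type mean, the X minus autosome difference in median log2 CPM was 0.39, 0.33 and 0.31 in the mutant libraries and 0.02, 0.02 and -0.04 in the wild-type ones. Among called genes, 32 X-linked ones rose and 5 fell in edgeR, and 203 autosomal ones rose and 108 fell. Rises made up 1.59% of X-linked and 1.82% of autosomal genes, and falls 0.25% and 0.97%. The limma camera adjusted p for chromosome X was 0.0063, and 0.018 with an estimated correlation. Chromosome V also ranked higher, with a median of 0.13 over 2768 genes, 82 risen and 16 fallen (limma camera adjusted p = 0.026, and 0.017 with an estimated correlation; 0.079 without wild-type library 1, range over the alternatives 0.0017 to 0.079). Chromosomes I and III ranked lower, with medians of -0.24 and -0.23 (limma camera adjusted p = 0.0089 for both, and 0.018 and 0.017 with an estimated correlation). Under library totals or the authors' normalized table these 2 medians turned positive, reaching 0.12 and 0.13, and relative to the median of the tested genes they stayed between -0.23 and -0.20. Against wild-type library 1 and against libraries 2 and 3 the medians in log2 CPM were 0.20 and 0.39 for X, 0.18 and 0.27 for V, -0.24 and -0.15 for I and -0.19 and -0.15 for III. Chromosomes II and IV, with medians of -0.08 and -0.09 that also changed sign, were not called, and their means, 0.08 and 0.06, were positive.

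Most genes that rose on autosomes lay on the arms, taken as the outer 2 of 3 equal segments of each chromosome. There 159 of 6331 genes rose and 28 fell, 2.51% and 0.44%, while in the middle segments 44 of 4810 rose and 80 fell, 0.91% and 1.66% (edgeR calls). The arm genes as a set did not pass limma's camera test (median 0.05, adjusted p = 0.077, and 0.29 with an estimated correlation; range over the alternatives 0.026 to 0.81). In limma's camera it passed without wild-type library 1 (adjusted p = 0.026) or mutant library 3 (0.037), and not without wild-type library 3 (0.37) or mutant library 2 (0.17) or against wild-type library 1 alone (0.81). In log2 CPM the arm median stood 0.25 higher in wild-type library 1 than in libraries 2 and 3, and the mutant median was -0.01 against library 1 and 0.25 against libraries 2 and 3. In the middle segments these values were -0.05, -0.12 and -0.25. Against library 1 alone edgeR called 115 arm genes (1.54%) and 41 middle genes (0.77%) higher.

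**Figure D3:**
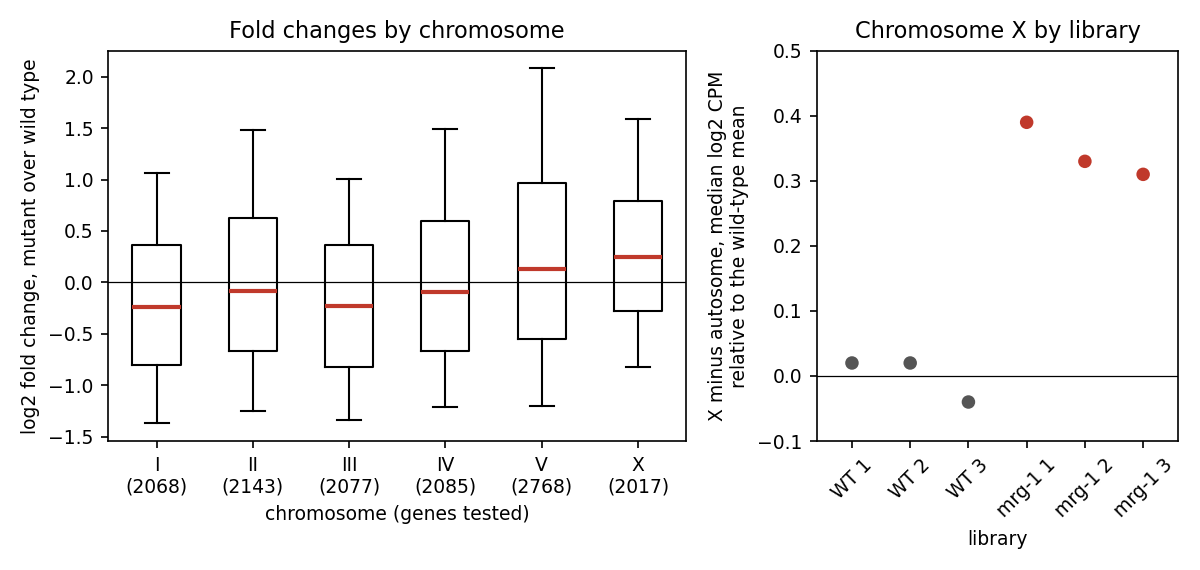
Left, log2 fold change (y axis, mutant over wild type, edgeR) of the tested genes by chromosome (x axis, number of genes in brackets); boxes span the quartiles, red lines are medians and whiskers reach percentiles 10 and 90. Right, the X minus autosome difference in median log2 CPM (y axis), relative to the wild-type mean, for each library (x axis), from 0.31 to 0.39 in the mutant (red) and from -0.04 to 0.02 in the wild type (grey); in the left panel, the medians of chromosomes I to IV change sign under other scalings.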

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

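Leaving out mitochondrial genes, thinning, quality weights and wild-type library 1 alone were chosen after the result was seen. No gene called in one direction was called in the other in any alternative. The count of changed genes (350, 236 higher and 114 lower) was 1534 (846 and 688) in DESeq2, 734 (434 and 300) without a filter, 215 (11 lower) under library totals. It was 30 (30 and 0 in edgeR) at an adjusted p of 0.01, and 44 (43 and 1) against a 2-fold minimum. In edgeR 2627 genes had an unadjusted p under 0.05, and DESeq2 was run at an adjusted p of 0.05 only. The authors' normalized table gave 480 and 34, quality weights 199 lower, and wild-type library 1 alone 74 lower. Leaving out each library gave 35 to 1043 genes, 35 to 559 higher and 0 to 484 lower. Deviations of same-numbered libraries correlated at 0.00, 0.04 and 0.09, and those of unlike numbers between the groups at -0.08 to 0.05. No clear sign of pairing by number was seen, though so few libraries cannot exclude it. With the replicate block 431 genes changed, 312 of them shared. The cause of these shifts was not tested. Leaving out a library leaves fewer samples, yet the count rose to 1043 without wild-type library 1 and to 403 without wild-type library 3.

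The log2 fold change of *mrg-1* was -2.06 (edgeR adjusted p = 0.105) under library totals, -2.0 (limma, 0.0761) in the authors' normalized table and -2.33 at the 0.01 threshold and against the 2-fold minimum (0.205), -2.54 to -1.99 over left-out libraries. Its adjusted p ranged from 0.000267 to 0.205. Of 72 named genes 13 passed at 0.01, 22 against the 2-fold minimum, 34 with wild-type library 1 alone and 14 to 68 over left-out libraries. List calls (10) numbered 0 with an estimated correlation, 4 in fry and 5 to 8 over left-out libraries. Family calls (11) numbered 0 with an estimated correlation and 8 in fry. Chromosome calls (4) numbered 2 in fry. In limma's fry, which asks whether a set moves one way and not how it ranks, the adjusted p was 0.07 and 0.058 for chromosomes I and III, 0.055 for collagens, 0.051 for F-box genes, 0.51 for ribosomal proteins, 0.088 for DNA replication, 0.12 for heterochromatin and 0.23 for P granules. The gene set insulin-like peptide family, not called in any other alternative, turned from lower to higher with wild-type library 1 alone (limma camera adjusted p = 0.0062, range 0.0062 to 1). Against library 1 alone the single wild-type sample is assumed to vary like the mutant ones. DESeq2, voom, robust, threshold and 2-fold alternatives give no value for the gene set tests. Genes under about 4-fold change are mostly beyond reach at this depth and spread.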

Other observations

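The library 1 differences and neighbouring genes in this and the next paragraph were singled out after their values were seen; the tests of each of the 3 immune lists alone, and the bound of 0.17 used for wild-type variation on chromosome X in place of 0.09, and the values of arm and middle genes by library, were chosen after the result was seen too. Neuropeptide-like, FMRFamide-like and transthyretin-related genes set wild-type library 1 apart from the other wild-type libraries. The neuropeptide-like family is defined by symbol and by that rule takes in *nlp-29* and *nlp-31*, which the immune list names. Library 1 lay below libraries 2 and 3 by a median log2 CPM difference of -0.98 over 61 neuropeptide-like protein genes, -0.75 over 29 FMRFamide-like peptide genes and -1.36 over 47 transthyretin-related genes, and above them by 1.22 over 55 collagens and 0.96 over 22 molting genes. Against library 1 alone the mutant medians of the first 3 families were 0.78, 0.84 and 0.90. Against libraries 2 and 3 they were 0.00, -0.08 and -0.26. None of these 3 families was called over all 6 libraries (limma camera adjusted p = 0.2, 0.33 and 0.64), and all 3 were called against library 1 alone (6.8e-08, 0.00027 and 1.7e-06; highest over the alternatives 0.9, 0.9 and 0.95).

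Some genes that rose were neighbours among the tested genes, among them *irg-5* of the immune list. Genes that were not tested can lie between such neighbours. On chromosome IV, *C32H11.4* and *dod-24* lay together between 12921264 and 12941354, and *F55G11.7* and *F55G11.8* between 12960436 and 12964645; on chromosome V, *F35E12.6* and *irg-5* lay between 13734309 and 13738474.

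Over the 152 tested immune effectors, C-type lectins and *pals* genes, 27 were higher and 1 lower, with a median log2 fold change of 0.87. A scaling to totals that hold mitochondrial RNA would need this median to fall below 0.44 under another scaling, and the lowest was 0.85 (95% bootstrap interval 0.57 to 1.33). This prediction decides nothing, because a scaling moves genes nearly alike. The median of all tested genes went from -0.03 to between -0.05 and 0.35, so no scaling tried could have reached 0.44. Relative to all tested genes, the lowest median of the members over the scalings was 0.80. Weakly expressed genes did lie higher: the median was 0.31 over the 4487 tested genes of lowest expression. It was -0.15 and -0.09 over those of middle and highest expression. Such a drift alone would need expression-matched lists to reach the members' 0.87, and 0 of 10000 did (median 0.04, highest 0.47). These lists were drawn gene by gene and so vary less than lists of related genes that move together would. The members also come from lists called higher in these same data. A drift shared by related genes was not tested. Poorer RNA or lower complexity of wild-type libraries 2 and 3 would need library 1 to exceed them by at least 0.5 of the mutant difference. The share was 0.24 over all members (95% interval 0.02 to 0.50), 0.02 for immune effectors (-0.21 to 0.45) and -0.10 for *pals* genes (-0.39 to 0.25). For these 2 lists this argues against a lack particular to libraries 2 and 3 in the libraries at hand. For C-type lectins the share was 0.52 (0.18 to 1.32), so such a lack remains open there. Lower complexity of all 3 wild-type libraries is not tested by this contrast. Thinned to one nuclear depth, wild-type libraries 1, 2 and 3 covered 15454, 13966 and 14880 genes, and the mutant libraries 15930, 16830 and 16710. The intervals in this paragraph resample genes as if independent and do not cover variation between libraries. An effect of the *mrg-1* genotype, and the picking of mutant mothers against washing of wild-type ones, may each account for the pattern and cannot be told apart in this design.

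The X minus autosome difference of 0.35 remained 0.35 after autosomal genes were matched on expression and length (interval 0.30 to 0.39), so these properties do not account for it. Variation among wild-type libraries would need a difference of at least 0.17 between library 1 and libraries 2 and 3, and it was 0.04 (interval -0.02 to 0.10), which argues against it as the whole cause. That interval resamples genes and does not cover variation between libraries. More neuronal and muscle RNA in the mutant remains open. The difference was 0.347 without the members of those lists, but only 64 of the 2017 X-linked genes were members, too few to move a median. A hypothesis is that loss of MRG-1 may raise X-linked expression slightly in these larvae, though picking and washing of the mothers differed between the groups too.

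A further hypothesis is that genes on autosome arms may be more prone to rise in the mutant than genes in the middle segments. The 159 risen genes on the arms exceeded each of 10000 shuffles of the calls within expression bins (0 reached it, median 115, highest 141). Expression level alone, with calls moved gene by gene, did not give this number. The shuffles do not keep neighbouring or related genes together and so vary less than clustered calls would. Whether clustered gene families account for the excess on the arms was not tested. Differences among the wild-type libraries remain open as a cause. The arm median was 0.25 higher in library 1 than in the mean of libraries 2 and 3, which also differed from each other. The mutant lay 0.25 above that mean but -0.01 from library 1. Against library 1 alone 1.54% of arm and 0.77% of middle genes still rose in edgeR. Risen genes were also neighbours among the tested genes in 21 pairs, against a median of 4 and a highest of 14 in 10000 shuffles. Of these pairs 9 shared no name stem, a number that 1.01% of the shuffles reached. The stem is the part of a symbol before its first hyphen or dot, so related genes under different names count as unrelated. The 9 pairs therefore do not settle whether clusters of related genes account for the neighbours.

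Among the 10 splits of the 6 libraries into 3 and 3, the real one gave 350 genes and the highest other gave 0, and 1 split, the real one, gave as many. With 10 splits a share under 0.05 cannot be reached.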
